A study of Mus musculus with 27 samples.

How the data were processed

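RNA had been taken from Cas9-expressing mouse bone-marrow-derived macrophages transduced with a targeting or non-targeting guide and treated with 4T1 tumour-conditioned medium. Per the labels, RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit. The authors' processing notes name STAR 2.6.1d, Salmon 0.13.1 and DESeq2 1.34.0, without their roles or order, and the builds GRCm38 and mm10. A deposited table held the authors' estimated counts per gene symbol (expected counts), of which some were fractional and none normalized. A second deposited table held TPM for the same 55291 symbols. Each mapped count column matched the TPM column of the same name best, for 27 of 27 libraries. A further 6 columns per table, which the labels did not map to these samples, were not used. Depth ran from 14042494 to 22385715 counts per library. Batch and group came from the labels and column names, and only the 6 columns of batch 0 end in the replicate numbers of the labels. In the other batches 1 column of each group has no such ending, so replicate names there follow column order.

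Counts were rounded, which changed 9.31% of values by at most 0.5. Genes were filtered with filterByExpr (at least 10 counts in the smallest group's libraries after scaling, and 15 in total). Libraries were scaled with TMM. For each batch 1 quasi-likelihood model with robust dispersion was fitted with edgeR 4.0.16 (R 4.3.3) to all libraries of that batch, with 1 mean per group. Each target group was then tested against the control group of its own batch. All p-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of a comparison, and genes with an adjusted p under 0.05 were called, with no minimum fold change. The SE of a log2 fold change was its size divided by the root of the F statistic. CPM values were scaled within the batch, except those of the control groups of all batches, which were scaled over the 9 control libraries.

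Gene lists (37, covering pathways, complexes, cell types and RNA quality) were written before the data were examined, as were the comparisons, the tests and most alternatives. They were tested with camera in limma 3.58.1 on log-CPM (prior count 2) with a preset correlation of 0.01. P-values were adjusted over all lists and the 6 comparisons together, and for the difference of sgLamtor1 and sgFlcn over its 33 lists. Lists with fewer than 5 genes after filtering were left out of the test, and a guide's own target was left out of its lists. The response to sgLamtor1 minus the response to sgFlcn was tested in 1 edgeR model of all 27 libraries, and differences between the control groups with an F test on the 9 control libraries. Similarity of targets was the Pearson correlation of log2 fold changes over genes tested for both. For pairs in the same batch, which share controls, it was set beside 20 simulations of groups without effects.

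Genes were named by rules set in advance. The rules took the 6 targets in every comparison, the 10 largest rises and falls among called genes with a mean CPM of at least 5 and no overlap between the groups, up to 4 members of each called list with the smallest adjusted p, 9 macrophage genes, and 10 shared and 10 differing genes for sgLamtor1 and sgFlcn. The text names the first 5 of each direction, except that results needing items withheld for evaluation are not reported here. For groups with 0 counts a bound was taken from a floor of 3 counts over the group, and for 1 to 3 counts a ratio with a 95% counting interval. Gene positions came from GENCODE vM21.

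The test was tried on simulated data built from each comparison's own counts, with 200 changed genes. Of changes of 1.5-fold, 2-fold and 4-fold, edgeR found 67.2%, 86.6% and 97.0% (12571 genes) for the sgLamtor1 design, 61.2%, 70.1% and 87.9% (12762 genes) for sgFlcn, 52.2%, 86.6% and 90.9% (12766 genes) for sgRreb1, 19.4%, 52.2% and 84.8% (13099 genes) for sgPpp2r3c, 20.9%, 64.2% and 80.3% (13116 genes) for sgPtger4 and 23.9%, 59.7% and 80.3% (13143 genes) for sgHif1a. All called changes had the right sign. The share of false calls was 10.0%, 5.29%, 6.99%, 5.26%, 5.79% and 5.08% in the same order, above the nominal 5% in each.

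Alternatives were other scaling (RLE), no filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, 1 model of all 27 libraries, a model of only the 6 libraries compared, a replicate block in batch 0, log2(TPM + 1) with limma, stricter thresholds, each library left out in turn, camera with an estimated correlation and the rotation test fry. Chosen after the data were seen were a removal of trends with effective transcript length, a block by column ending and, for sgPpp2r3c and sgPtger4, a model without sgHif1a replicate 1.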

Results

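Poly(A) RNA was sequenced from mouse bone-marrow-derived macrophages that carried a Cas9 gene at the Rosa26 locus. The cells had been transduced with guide RNAs (sgRNAs) and then exposed to medium conditioned by 4T1 cells, a mouse mammary carcinoma line. The 27 libraries formed 9 groups of 3 in 3 batches, each batch with its own non-targeting control group (sgNC). Batch 0 held sgNC_batch0 and sgLamtor1. Batch 1 held sgNC_batch1, sgFlcn and sgRreb1, and batch 2 held sgNC_batch2, sgPpp2r3c, sgPtger4 and sgHif1a. Total counts per library ran from 14845736 to 18400991 in batch 0, 14042494 to 21242813 in batch 1 and 17438822 to 22385715 in batch 2. Between replicates, the SD of the log2 difference over genes lay between 0.137 and 0.307 in 25 of 27 pairs. It was 0.580 and 0.551 in the pairs with sgHif1a replicate 1. The labels did not say whether replicates were separate cultures or animals, so p-values measure the spread between these samples.

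Each guide's own target was examined first, as counts scaled to library size (CPM, mean ± SD, n = 3 libraries per group here and throughout). On the GRCm38 assembly with GENCODE vM21 annotation, the 6 protein-coding targets were Lamtor1 (chromosome 7, 101905904 to 101926675, plus strand), Flcn (chromosome 11, 59791408 to 59810016, minus strand), Rreb1 (chromosome 13, 37778400 to 37952005, plus strand), Ppp2r3c (chromosome 12, 55278991 to 55302998, minus strand), Ptger4 (chromosome 15, 5206661 to 5244187, minus strand) and Hif1a (chromosome 12, 73901375 to 73947530, plus strand). Lamtor1 fell under its guide from 102 ± 4.63 to 52.1 ± 2.91 CPM, a log2 fold change of -0.97 (SE 0.067, edgeR adjusted p = 9.58e-10). Flcn fell under its guide from 127 ± 3.53 to 87.4 ± 2.59 CPM (log2 fold change -0.54, SE 0.061, edgeR adjusted p = 3.22e-06). Hif1a fell under its guide from 835 ± 107 to 267 ± 13.2 CPM (log2 fold change -1.64, SE 0.11, edgeR adjusted p = 7.59e-07). Rreb1 stood at 144 ± 4.73 CPM under its guide and 146 ± 16.9 CPM in controls, with a log2 fold change of -0.029 (SE 0.077, edgeR adjusted p = 0.799). Ppp2r3c stood at 17.7 ± 0.562 and 19.9 ± 2.09 CPM, with a log2 fold change of -0.18 (SE 0.18, edgeR adjusted p = 0.693). An edit can leave mRNA abundance as it was, so the mRNA did not check the labels sgRreb1 and sgPpp2r3c. Ptger4 mRNA rose in the libraries labelled sgPtger4, from 45.4 ± 7.47 to 78.3 ± 6.01 CPM, a log2 fold change of 0.79 (SE 0.12, edgeR adjusted p = 0.0011). That direction is opposite to a loss of the transcript, so every direction given for this group rests on the label.

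**Figure D1:**
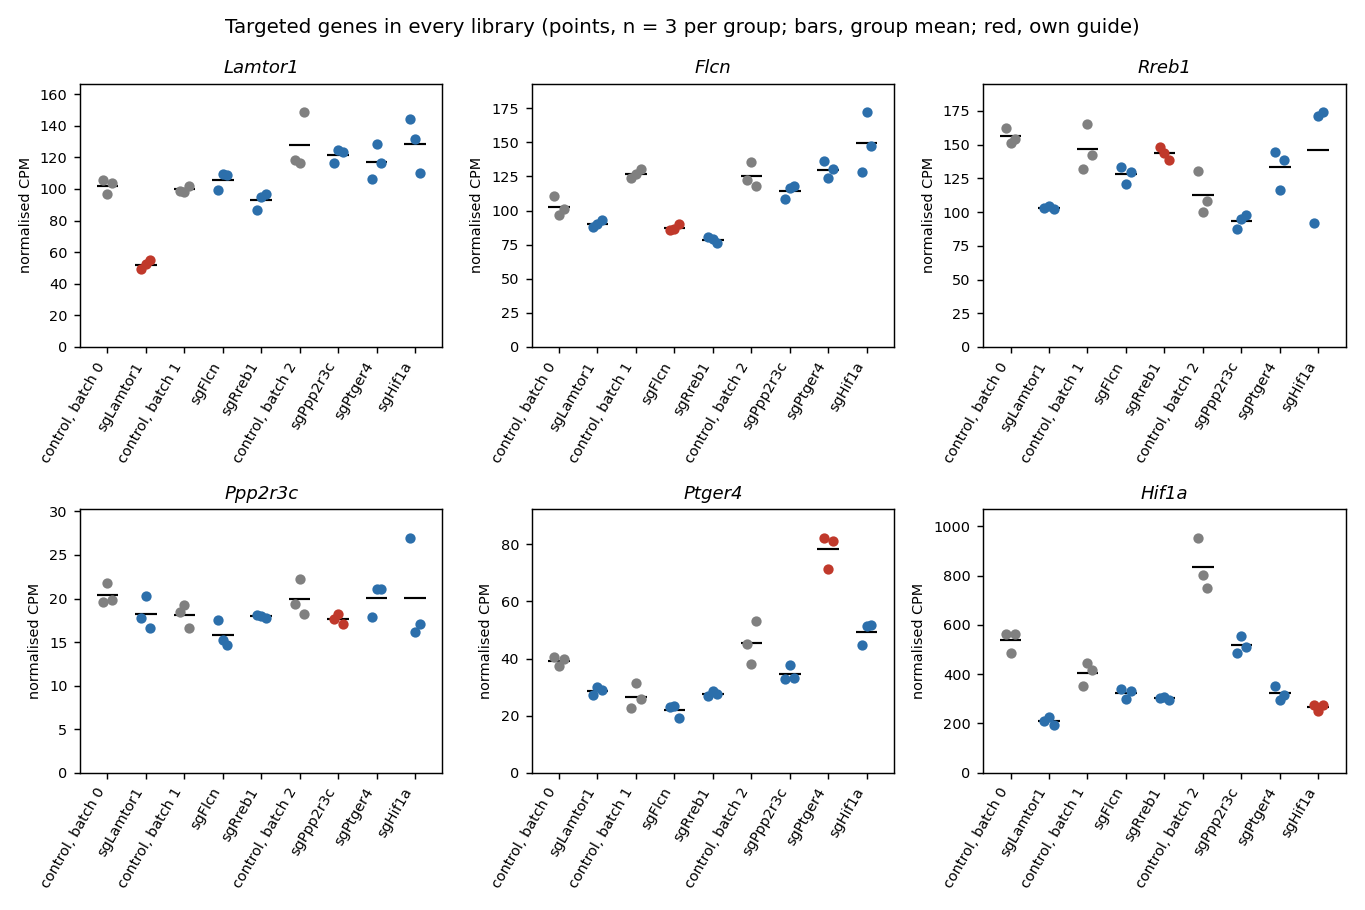
CPM of the 6 targeted genes (linear axes from 0) in each of the 27 libraries by group. Points are libraries and bars are group means, and values given here are mean ± SD. Hif1a lay at 835 ± 107 CPM in sgNC_batch2 and 267 ± 13.2 CPM under its own guide, while Ptger4 was higher under its own guide than in sgNC_batch2.

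Targeted genes also responded to other guides. Hif1a mRNA fell in all 6 comparisons, including sgLamtor1 (log2 fold change -1.36, SE 0.073, edgeR adjusted p = 6.72e-11), sgFlcn (log2 fold change -0.32, SE 0.081, edgeR adjusted p = 0.00492), sgRreb1 (log2 fold change -0.43, SE 0.081, edgeR adjusted p = 0.000693), sgPpp2r3c (log2 fold change -0.69, SE 0.11, edgeR adjusted p = 0.000989) and the libraries labelled sgPtger4 (log2 fold change -1.37, SE 0.11, edgeR adjusted p = 2.92e-06). Flcn fell under sgRreb1 (log2 fold change -0.69, SE 0.061, edgeR adjusted p = 4.06e-07), a larger fitted change than the -0.54 under its own guide, though the difference was not tested. Under sgLamtor1, Rreb1 fell (log2 fold change -0.60, SE 0.057, edgeR adjusted p = 7.98e-08) and Ptger4 (log2 fold change -0.45, SE 0.085, edgeR adjusted p = 0.000258). Flcn fell there (log2 fold change -0.19, SE 0.064, edgeR adjusted p = 0.0212), and edgeR no longer called it without sgNC_batch0 replicate 1 (adjusted p = 0.14), sgNC_batch0 replicate 3 (0.0514) or sgLamtor1 replicate 1 (0.0982). Rreb1 and Ptger4 were not called under sgFlcn, at -0.19 (0.0596) and -0.29 (0.0645) as log2 fold change and edgeR adjusted p, but both were called lower without sgNC_batch1 replicate 1 (edgeR adjusted p = 0.0124 and 0.0133). Ptger4 under sgPpp2r3c was at -0.39 (0.0929), and was called lower without sgNC_batch2 replicate 2 (edgeR adjusted p = 0.0398). Flcn and Rreb1 under sgHif1a were at 0.25 (0.253) and 0.37 (0.421), and were called higher without sgHif1a replicate 1 (edgeR adjusted p = 0.0137 and 0.000573). The other targets off their own guides were not called, with edgeR adjusted p from 0.151 (Ppp2r3c under sgFlcn) to 0.995 (Ppp2r3c under sgHif1a).

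Lists of genes fixed in advance were tested with camera at a preset correlation of 0.01, with adjustment over 193 tests, and 71 were called. With an estimated correlation 16 of these calls held. They were the lysosome list under sgLamtor1 and sgFlcn, cholesterol biosynthesis and MHC class II under sgFlcn, p53 targets under sgRreb1, and HIF-1 and NF-kB targets under sgPpp2r3c. The others were glycolysis, HIF-1 targets, tumour-associated macrophage genes and p53 targets in the libraries labelled sgPtger4, and glycolysis, HIF-1 targets, NF-kB targets, tumour-associated macrophage genes and the cell cycle under sgHif1a.

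**Figure D2:**
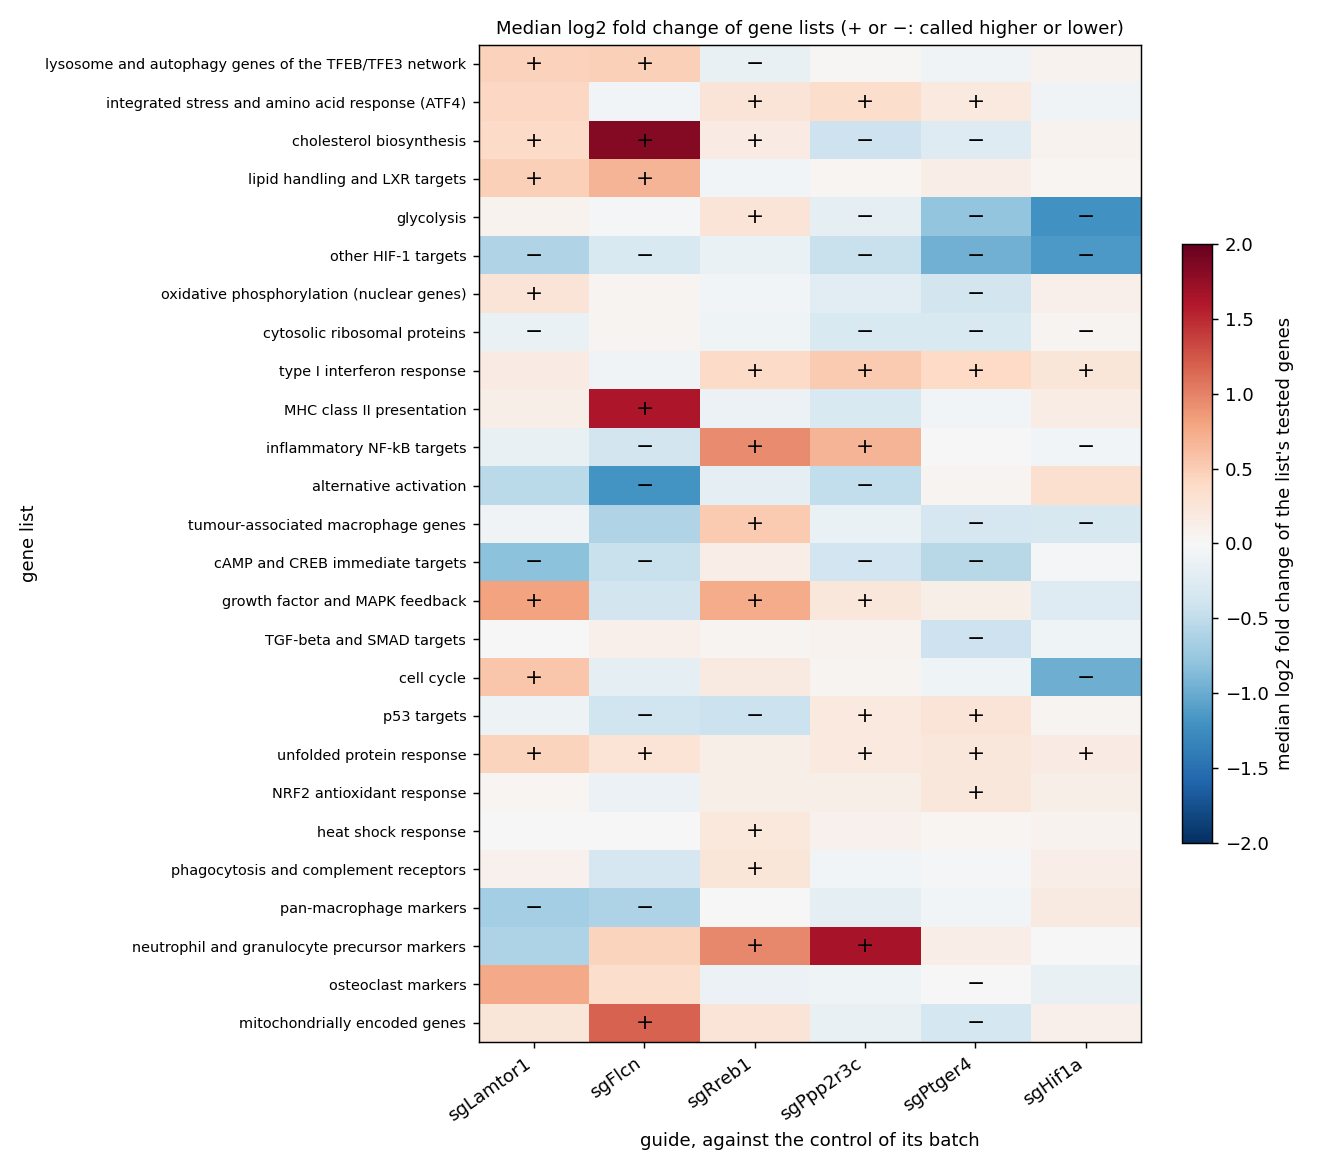
Median log2 fold change (color) of 26 gene lists in the 6 comparisons of target with same-batch control, with + and − for lists that camera called higher or lower. Glycolysis genes had medians of -1.21 under sgHif1a and -0.79 in the libraries labelled sgPtger4; on the TPM scale 4 of the 71 called medians change sign (cholesterol biosynthesis and osteoclast markers in sgPtger4, ribosomal proteins and NF-kB targets in sgHif1a).

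LAMTOR1 is a subunit of the Ragulator complex, which holds the Rag GTPases and the growth regulator mTORC1 at the lysosome surface. The comparison of sgLamtor1 with sgNC_batch0 asked which transcripts in tumour-exposed macrophages depended on it. Of 12949 genes tested with edgeR, 3367 rose and 3265 fell, and 7297 had an unadjusted p under 0.05. Mgll, the gene for monoacylglycerol lipase, had the largest rise, from 0.388 ± 0.0789 to 146 ± 12.8 CPM, a log2 fold change of 8.50 (SE 0.14, edgeR adjusted p = 1.80e-18). Fstl1, which encodes a secreted glycoprotein, rose by 7.20 (SE 0.12, edgeR adjusted p = 1.10e-16), and Dio2, a deiodinase that activates thyroid hormone, by 6.57 (SE 0.11, edgeR adjusted p = 1.38e-16). Cdo1, a cysteine dioxygenase, rose by 5.92 (SE 0.27, edgeR adjusted p = 2.24e-12) and the integrin gene Itgb3 by 5.70 (SE 0.24, edgeR adjusted p = 5.33e-07). Among the falls, Plxdc2, a plexin-domain membrane protein, fell (log2 fold change -5.55, SE 0.20, edgeR adjusted p = 1.07e-13) and the membrane protein gene Ms4a4a (log2 fold change -4.40, SE 0.11, edgeR adjusted p = 5.14e-14). Arg1, which encodes arginase 1 and is high in macrophages exposed to tumours, fell from 88.0 ± 18.8 to 5.33 ± 0.848 CPM (log2 fold change -4.04, SE 0.21, edgeR adjusted p = 2.18e-06), and the cytokine gene Il1b fell from 110.4 ± 7.11 to 8.29 ± 1.89 CPM (log2 fold change -3.73, SE 0.11, edgeR adjusted p = 5.77e-13). Fam177a2 had 0 counts under sgLamtor1 and 1869 in controls, at least 562-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0297, and 0.151 without sgNC_batch0 replicate 3). Floors and intervals from counts cover counting error only. The fall of Fam177a2 was uncertain, because its paralog Fam177a stood at 81.0 ± 4.60 against 41.0 ± 20.01 CPM (edgeR adjusted p = 0.133) and their sum lay between 75.7 and 83.9 CPM in all 6 libraries.

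Among other macrophage genes fixed in advance, the matrix protein gene Spp1 rose under sgLamtor1 from 719.7 ± 209.5 to 5635 ± 474 CPM (log2 fold change 2.97, SE 0.25, edgeR adjusted p = 0.000785) and the glycoprotein gene Gpnmb from 9669.7 ± 123 to 27608 ± 557 CPM (log2 fold change 1.51, SE 0.051, edgeR adjusted p = 4.88e-14). Cd274, which encodes the checkpoint ligand PD-L1, rose by 0.68 (SE 0.057, edgeR adjusted p = 1.45e-08) and the MHC class II gene H2-Ab1 by 0.89 (SE 0.20, edgeR adjusted p = 0.0121). Vegfa, an angiogenic growth factor, fell (log2 fold change -1.65, SE 0.15, edgeR adjusted p = 3.78e-05) and the mannose receptor gene Mrc1 (log2 fold change -1.07, SE 0.075, edgeR adjusted p = 5.72e-09). Nos2, the inducible nitric oxide synthase, was not called at 0.54 (SE 0.21, edgeR adjusted p = 0.069), and was called higher without sgNC_batch0 replicate 2 (edgeR adjusted p = 0.00614).

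The transcription factors TFEB and TFE3 drive lysosomal and autophagy genes, and of 48 such genes 38 rose and 5 fell (38 and 5 adjusted over the list alone) under sgLamtor1 (camera adjusted p = 7.51e-09, and adjusted p = 0.0404 with an estimated correlation). Among them, Rragd, a Rag GTPase, and Ctsd, the protease cathepsin D, rose by 2.68 and 1.29. Of 35 cell cycle genes, 31 rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 2.05e-07, and adjusted p = 0.491 with an estimated correlation). The replication helicase genes Mcm2 and Mcm3 rose by 1.15 and 0.86. Of 23 cholesterol biosynthesis genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 0.000343, and adjusted p = 0.0853 with an estimated correlation). Sqle rose by 1.04. Of 23 lipid handling genes, 16 rose and 4 fell (16 and 4 adjusted over the list alone, camera adjusted p = 0.00638, and adjusted p = 0.227 with an estimated correlation). The fatty acid binding protein gene Fabp4 rose by 3.48. Of 16 growth factor and MAPK feedback genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00504, and adjusted p = 0.49 with an estimated correlation). Myc rose by 2.22. Of 20 unfolded protein response genes, 13 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00179, and adjusted p = 0.301 with an estimated correlation). The chaperone gene Hspa5 rose by 0.85. Nuclear oxidative phosphorylation genes had a median of 0.26, and 30 rose and 0 fell (30 and 0 adjusted over the list alone) of 59 (camera adjusted p = 0.000582, and adjusted p = 0.49 with an estimated correlation).

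Lists that fell under sgLamtor1 included 19 cAMP and CREB targets, of which 4 rose and 12 fell (4 and 13 adjusted over the list alone, camera adjusted p = 0.00381, and adjusted p = 0.154 with an estimated correlation). The phosphodiesterase gene Pde3b fell (log2 fold change -2.24) and Fos fell (log2 fold change -0.99). Of 23 HIF-1 targets outside glycolysis, 3 rose and 14 fell (3 and 15 adjusted over the list alone, camera adjusted p = 0.00342, and adjusted p = 0.346 with an estimated correlation). The mitophagy gene Bnip3 fell (log2 fold change -1.27, SE 0.082, edgeR adjusted p = 4.36e-10). Of 15 pan-macrophage markers, 3 rose and 9 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.227 with an estimated correlation). Csf1r, the receptor for the survival factor CSF1, fell from 3808 ± 258 to 1243 ± 24.9 CPM. Of 75 cytosolic ribosomal protein genes, 8 rose and 32 fell (8 and 32 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0295, and adjusted p = 0.671 with an estimated correlation), a call that ended without sgLamtor1 replicate 2 (camera adjusted p = 0.11).

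FLCN (folliculin) is a GTPase-activating protein for Rag GTPases at the lysosome, where it lets mTORC1 phosphorylate TFEB and TFE3. Comparing sgFlcn with sgNC_batch1 asked which transcripts changed with this guide. Of 13259 genes tested with edgeR, 2507 rose and 2517 fell, and 6154 had an unadjusted p under 0.05. Mgll had 7476 counts under sgFlcn and 2 in controls, a ratio of 3583 with a 95% counting interval of 991 to 29589. Tspan7, a tetraspanin gene, had 514 counts against 2, a ratio of 246 with an interval of 67.8 to 2039. Fstl1 rose by 8.74 (SE 0.17, edgeR adjusted p = 1.78e-15), Itgb3 by 7.39 (SE 0.18, edgeR adjusted p = 2.06e-14) and the MHC class II gene H2-Aa by 6.89 (SE 0.18, edgeR adjusted p = 5.59e-14). The neutrophil-attracting chemokine genes Ppbp (log2 fold change -5.70, SE 0.10, edgeR adjusted p = 1.38e-15), Cxcl5 (log2 fold change -4.29, SE 0.21, edgeR adjusted p = 1.28e-10) and Cxcl3 (log2 fold change -3.92, SE 0.13, edgeR adjusted p = 1.59e-11) fell. Arg1 fell from 912 ± 63.8 to 43.6 ± 4.55 CPM (log2 fold change -4.39, SE 0.087, edgeR adjusted p = 2.07e-15), and Plxdc2 fell (log2 fold change -4.36, SE 0.25, edgeR adjusted p = 4.68e-09). Gpnmb rose from 7453 ± 215 to 34804 ± 1873 CPM (log2 fold change 2.22, SE 0.059, edgeR adjusted p = 8.34e-14) and Spp1 by 1.42 (SE 0.16, edgeR adjusted p = 9.30e-05). Cd274 rose by 1.05 (SE 0.078, edgeR adjusted p = 2.26e-08), Il1b fell (log2 fold change -1.88, SE 0.14, edgeR adjusted p = 2.54e-08) and Mrc1 fell from 997 ± 16.3 to 333 ± 16.0 CPM. Vegfa was not called at 0.097 (SE 0.11, edgeR adjusted p = 0.526), and neither was Nos2 at 0.32 (SE 0.13, edgeR adjusted p = 0.0663), which edgeR called higher without sgNC_batch1 replicate 1 (adjusted p = 0.0429) or sgFlcn replicate 3 (0.0196).

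Cholesterol biosynthesis moved together under sgFlcn, where 22 rose and 0 fell (22 and 0 adjusted over the list alone) of 23 genes, with a median of 1.83 (camera adjusted p = 2.56e-17, and adjusted p = 0.0339 with an estimated correlation). Sqle, which encodes squalene epoxidase, rose from 8.68 ± 0.249 to 80.4 ± 6.93 CPM. Of 48 lysosome and autophagy genes, 34 rose and 2 fell (34 and 2 adjusted over the list alone, camera adjusted p = 1.08e-10, and adjusted p = 0.0404 with an estimated correlation). The vacuolar ATPase gene Atp6v0d2 rose by 5.64 (SE 0.13, edgeR adjusted p = 2.06e-14). Among 11 MHC class II genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.62 (camera adjusted p = 1.69e-05, and adjusted p = 0.0404 with an estimated correlation). H2-Ab1 rose from 8.66 ± 0.279 to 62.8 ± 5.09 CPM and Cd74, the class II chaperone, from 8.79 ± 0.815 to 65.6 ± 0.870 CPM. Of 23 lipid handling genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 7.15e-05, and adjusted p = 0.0545 with an estimated correlation). The desaturase gene Scd2 rose by 4.79 and Fabp4 rose by 4.48. Of 22 p53 targets, 3 rose and 13 fell (3 and 13 adjusted over the list alone, camera adjusted p = 0.00179, and adjusted p = 0.0689 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a fell from 788 ± 27.6 to 320.0 ± 19.7 CPM. Of 15 pan-macrophage markers, 4 rose and 10 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.00599, and adjusted p = 0.232 with an estimated correlation). The endotoxin co-receptor gene Cd14 fell (log2 fold change -1.11). Mitochondrially encoded genes had a median of 1.18, and 5 rose and 0 fell (5 and 0 adjusted over the list alone) of 15 (camera adjusted p = 0.00013, and adjusted p = 0.49 with an estimated correlation). Their share of counts was 0.749%, 1.90% and 0.869% in sgNC_batch1 replicates 1, 2 and 3, and 1.89% to 2.29% in sgFlcn.

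Further lists under sgFlcn were called less firmly. Of 28 NF-kB targets, 6 rose and 14 fell (7 and 14 adjusted over the list alone, camera adjusted p = 0.0307, and adjusted p = 0.54 with an estimated correlation). The chemokine gene Cxcl2 fell (log2 fold change -2.17). Of 15 alternative activation genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.0155, and adjusted p = 0.157 with an estimated correlation). The interleukin-4 receptor gene Il4ra fell (log2 fold change -1.21). Of 19 cAMP targets, 4 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.0448, and adjusted p = 0.436 with an estimated correlation), and of 24 HIF-1 targets, 3 rose and 14 fell (3 and 14 adjusted over the list alone, camera adjusted p = 0.0139, and adjusted p = 0.227 with an estimated correlation). The collagen hydroxylase gene P4ha2 fell (log2 fold change -1.04). Of 20 unfolded protein response genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0105, and adjusted p = 0.41 with an estimated correlation). These calls ended when 1 library was left out (camera adjusted p in parentheses): without sgNC_batch1 replicate 2, HIF-1 targets (0.0539), NF-kB targets (0.068), alternative activation (0.0579), cAMP targets (0.116) and unfolded protein response (0.053); without sgNC_batch1 replicate 3, cAMP targets (0.0608); without sgFlcn replicate 2, cAMP targets (0.0625); without sgFlcn replicate 3, NF-kB targets (0.0521). The number of called lists went from 12 to 7 without sgNC_batch1 replicate 2.

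LAMTOR1 and FLCN both act on Rag GTPases at the lysosome, so their effects were set side by side. Across 12669 genes tested in both, log2 fold changes had a Pearson r of 0.61. This r is across genes, which are not independent replicates. Of these genes 1610 rose in both and 1429 fell in both, where independent lists would share 643 and 619, and 327 were called in opposite directions. The shared genes with the firmest calls included Arfgef3 at 4.65 and 6.71, the neuropeptide gene Npy at 2.71 and 4.16, the endocytic receptor gene Ly75 at 4.43 and 5.32 and Rragd at 2.68 and 3.13. Plpp3, a lipid phosphatase gene, and Clec4e, a receptor for mycobacterial glycolipid, rose by 3.87 and 3.63 under sgLamtor1 and by 4.30 and 3.24 under sgFlcn.

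**Figure D3:**
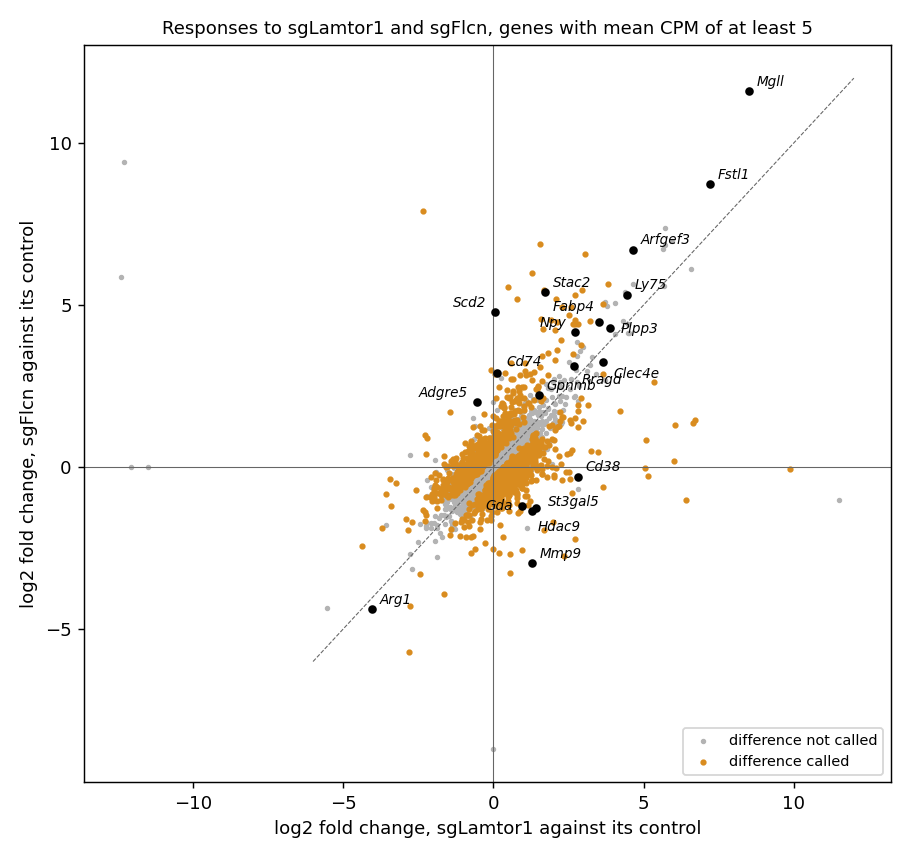
Log2 fold change under sgLamtor1 (x axis) against that under sgFlcn (y axis), both against same-batch controls; each of the 10012 points is a gene with a mean CPM of at least 5, and labelled genes are shared and differing genes. Pearson r over the 12669 genes tested in both was 0.61, and Scd2 lay at 0.073 under sgLamtor1 and 4.78 under sgFlcn.

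A fit of all 27 libraries tested the difference of both effects directly. Of 14363 genes, 1875 responded differently (edgeR, response to sgLamtor1 higher for 1047 and lower for 828), and 3861 had an unadjusted p under 0.05. Without sgNC_batch1 replicate 1 the count was 1151. Scd2 had the firmest difference, -4.71 (SE 0.13, edgeR adjusted p = 1.46e-19). Scd2 stood at 284 CPM in sgNC_batch0 and 299 under sgLamtor1, and at 17.7 in sgNC_batch1 and 486 under sgFlcn. The gelatinase gene Mmp9 differed by 4.27. Mmp9 rose by 1.30 under sgLamtor1 and fell under sgFlcn, to -2.97 in this fit. The NAD glycohydrolase gene Cd38 differed by 3.13 and Cd74 by -2.76. Of 33 lists 15 differed, and 3 of these also did with an estimated correlation. Cholesterol biosynthesis had the smallest camera adjusted p of them, with median log2 fold changes of 0.39 and 1.83 (camera adjusted p = 6.20e-27, and adjusted p = 9.96e-05 with an estimated correlation). MHC class II genes had medians of 0.14 and 1.62 (camera adjusted p = 1.98e-05, and adjusted p = 0.0194 with an estimated correlation). Cell cycle genes had medians of 0.57 and -0.20 (camera adjusted p = 2.37e-14, and adjusted p = 0.147 with an estimated correlation). The lysosome list had medians of 0.49 and 0.48 and its difference was not called (camera adjusted p = 0.918). Each guide came from a different batch, so batch and target cannot be told apart in this comparison.

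RREB1 is a zinc finger transcription factor that binds Ras-responsive elements. The sgRreb1 comparison, also against sgNC_batch1, asked which macrophage transcripts changed with this guide. Of 13259 genes tested with edgeR, 2501 rose and 2310 fell, and 5993 had an unadjusted p under 0.05. The largest rises were in genes near 0 in controls. The tau kinase gene Ttbk1 rose from 0.467 ± 0.202 to 19.0 ± 0.567 CPM (log2 fold change 5.34, SE 0.26, edgeR adjusted p = 8.82e-10), and the microtubule genes Clip3 and Map6 rose by 5.11 (SE 0.30, edgeR adjusted p = 7.98e-09) and 4.79 (SE 0.21, edgeR adjusted p = 5.16e-10). Pkp3, a desmosome component, rose by 5.28 (SE 0.32, edgeR adjusted p = 8.71e-09), or 5.91 without sgNC_batch1 replicate 2. Armcx4 rose by 4.80 (SE 0.39, edgeR adjusted p = 3.92e-07), or 6.30 without sgNC_batch1 replicate 3. Apoe, the main apolipoprotein of macrophages, fell from 4205 ± 571 to 619 ± 80.1 CPM (log2 fold change -2.76, SE 0.20, edgeR adjusted p = 1.85e-05), and the lipoprotein receptor gene Vldlr fell (log2 fold change -3.29, SE 0.19, edgeR adjusted p = 5.53e-09). Tcp11l2 fell (log2 fold change -2.38, SE 0.12, edgeR adjusted p = 2.17e-09), and so did the acetyltransferase gene Nat8l (log2 fold change -2.29, SE 0.17, edgeR adjusted p = 5.57e-08). Nos2 rose from 34.1 ± 4.64 to 72.9 ± 8.75 CPM (log2 fold change 1.09, SE 0.12, edgeR adjusted p = 1.29e-05), Spp1 by 0.80 (SE 0.16, edgeR adjusted p = 0.00373) and Cd274 by 0.79 (SE 0.078, edgeR adjusted p = 1.17e-06). Arg1 fell (log2 fold change -0.71, SE 0.074, edgeR adjusted p = 2.54e-06), Vegfa (log2 fold change -0.92, SE 0.11, edgeR adjusted p = 3.30e-05), Gpnmb (log2 fold change -0.48, SE 0.056, edgeR adjusted p = 8.70e-06) and Mrc1 (log2 fold change -0.34, SE 0.060, edgeR adjusted p = 0.000369). H2-Ab1 rose by 0.43 (SE 0.13, edgeR adjusted p = 0.0131), and was not called without sgRreb1 replicate 2 (edgeR adjusted p = 0.0668) or replicate 3 (0.0543). Il1b was not called at 0.17 (SE 0.12, edgeR adjusted p = 0.318).

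Inflammatory genes rose under sgRreb1. Of 28 NF-kB targets, 21 rose and 4 fell (21 and 4 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 2.81e-07, and adjusted p = 0.227 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose from 10.0 ± 1.54 to 41.2 ± 5.81 CPM (log2 fold change 2.04, SE 0.15, edgeR adjusted p = 6.23e-08). Of 36 interferon response genes, 24 rose and 0 fell (24 and 0 adjusted over the list alone, camera adjusted p = 3.29e-07, and adjusted p = 0.346 with an estimated correlation). The transcription factor gene Irf7 rose by 0.68. Of 17 growth factor and MAPK feedback genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 1.86e-05, and adjusted p = 0.336 with an estimated correlation). Phlda1 rose by 2.57 and Myc rose by 2.39. Of 30 tumour-associated macrophage genes, 16 rose and 6 fell (17 and 7 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.369 with an estimated correlation). Fibronectin (Fn1) rose from 58.7 ± 9.68 to 260.3 ± 17.0 CPM. Of 18 glycolysis genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.00803, and adjusted p = 0.346 with an estimated correlation). The phosphofructokinase gene Pfkp rose by 0.90. In contrast to sgFlcn and sgLamtor1, of 48 lysosome genes 4 rose and 22 fell (4 and 23 adjusted over the list alone) under sgRreb1 (camera adjusted p = 0.000181, and adjusted p = 0.165 with an estimated correlation). Rragd fell (log2 fold change -1.25, SE 0.11, edgeR adjusted p = 3.12e-07); these contrasts between guides were not tested. Of 22 p53 targets, 1 rose and 14 fell (1 and 15 adjusted over the list alone, camera adjusted p = 1.29e-05, and adjusted p = 0.0385 with an estimated correlation). Trp53inp1 fell (log2 fold change -1.87).

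Weaker list calls under sgRreb1 were as follows. Of 27 ATF4 targets, 14 rose and 5 fell (16 and 7 adjusted over the list alone, camera adjusted p = 0.0499504, and adjusted p = 0.49 with an estimated correlation). The amino acid transporter gene Slc7a5 rose by 1.56. Of 23 cholesterol biosynthesis genes, 9 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0402, and adjusted p = 0.459 with an estimated correlation). Sqle rose by 1.43. Of 13 heat shock genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0396, and adjusted p = 0.346 with an estimated correlation), and of 20 phagocytosis genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0312, and adjusted p = 0.49 with an estimated correlation). The complement receptor gene C5ar1 rose by 1.11. Of 9 neutrophil markers, 7 rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0111, and adjusted p = 0.346 with an estimated correlation). The calprotectin gene S100a9 rose by 1.36. These calls ended when 1 library was left out (camera adjusted p in parentheses): without sgNC_batch1 replicate 1, phagocytosis (0.0844) and neutrophil markers (0.0798); without sgNC_batch1 replicate 2, ATF4 response (0.183), cholesterol biosynthesis (0.0545), heat shock (0.0692) and neutrophil markers (0.0666); without sgNC_batch1 replicate 3, heat shock (0.0638); without sgRreb1 replicate 1, ATF4 response (0.0511); without sgRreb1 replicate 3, ATF4 response (0.0659) and heat shock (0.061).

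PPP2R3C is a regulatory subunit of the phosphatase PP2A. Against sgNC_batch2, edgeR called 583 genes higher and 299 lower of 13587 under sgPpp2r3c, and 2448 had an unadjusted p under 0.05. The comparison asked which transcripts changed with this guide. Nes, the intermediate filament gene nestin, had the largest rise, from 0.317 ± 0.151 to 41.7 ± 1.31 CPM (log2 fold change 7.04, SE 0.27, edgeR adjusted p = 5.24e-09). The adhesion gene L1cam rose by 3.47 (SE 0.37, edgeR adjusted p = 0.000138), and Ch25h, which makes 25-hydroxycholesterol, by 3.41 (SE 0.31, edgeR adjusted p = 1.46e-05). Spn, the sialoglycoprotein CD43, rose from 37.0 ± 7.05 to 379.6 ± 12.5 CPM (log2 fold change 3.36, SE 0.15, edgeR adjusted p = 7.87e-09) and the collagen crosslinking gene Lox by 3.36 (SE 0.14, edgeR adjusted p = 5.56e-09). Fn1 fell (log2 fold change -2.21, SE 0.35, edgeR adjusted p = 0.0025), as did the growth factor gene Nrg1 (log2 fold change -1.91, SE 0.15, edgeR adjusted p = 3.80e-06) and the kynurenine hydroxylase gene Kmo (log2 fold change -1.78, SE 0.19, edgeR adjusted p = 4.22e-05). Arg1 fell from 1798 ± 187 to 451 ± 24.3 CPM (log2 fold change -1.996, SE 0.18, edgeR adjusted p = 1.18e-05) and Vegfa from 405 ± 34.9 to 198 ± 23.6 CPM (log2 fold change -1.03, SE 0.12, edgeR adjusted p = 8.76e-05). Nos2 rose by 1.03 (SE 0.21, edgeR adjusted p = 0.00701) and Spp1 by 0.95 (SE 0.17, edgeR adjusted p = 0.00422), and Mrc1 fell (log2 fold change -0.72, SE 0.11, edgeR adjusted p = 0.000688). H2-Ab1, Il1b, Gpnmb and Cd274 were not called, with log2 fold changes of -0.31, -0.13, -0.21 and -0.098. The 882 calls were 489, 525 and 511 without sgPpp2r3c replicate 1, 2 and 3 in turn, and 1824 without sgHif1a replicate 1, which shares the batch's fit.

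Of 28 NF-kB targets, 16 rose and 0 fell (17 and 0 adjusted over the list alone) under sgPpp2r3c, with a median of 0.68 (camera adjusted p = 5.50e-11, and adjusted p = 0.00326 with an estimated correlation). The cytokine gene Tnf rose from 6.001 ± 1.16 to 26.8 ± 0.631 CPM (log2 fold change 2.16, SE 0.17, edgeR adjusted p = 3.97e-06). Of 36 interferon response genes, 16 rose and 0 fell (27 and 0 adjusted over the list alone, camera adjusted p = 5.79e-15, and adjusted p = 0.0545 with an estimated correlation). The antiviral gene Rsad2 rose by 1.15. Of 27 ATF4 targets, 7 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 7.31e-05, and adjusted p = 0.134 with an estimated correlation). The cystine transporter gene Slc7a11 rose by 1.29. Of 21 p53 targets, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00638, and adjusted p = 0.0714 with an estimated correlation). The kinase gene Plk2 rose by 1.15. Of 24 HIF-1 targets, 1 rose and 9 fell (2 and 15 adjusted over the list alone, camera adjusted p = 4.94e-08, and adjusted p = 0.041 with an estimated correlation). The prolyl hydroxylase gene Egln3 fell from 123 ± 16.5 to 46.6 ± 4.85 CPM (log2 fold change -1.41, SE 0.13, edgeR adjusted p = 1.12e-05). Of 18 glycolysis genes, 2 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.00688, and adjusted p = 0.41 with an estimated correlation). Pfkl fell (log2 fold change -0.54). Of 23 cholesterol biosynthesis genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone, camera adjusted p = 8.26e-09, and adjusted p = 0.0853 with an estimated correlation). Ribosomal protein genes had a median of -0.31 (camera adjusted p = 0.000984, and adjusted p = 0.821 with an estimated correlation), while edgeR called 0 of 75, over all genes and over the list alone, and 15 lower without sgHif1a replicate 1 (camera adjusted p = 1.27e-11).

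Lists whose calls under sgPpp2r3c rested on single libraries were alternative activation, in which 1 rose and 4 fell (2 and 7 adjusted over the list alone) of 15 (camera adjusted p = 0.00799, and adjusted p = 0.0853 with an estimated correlation), and cAMP targets, in which 2 rose and 4 fell (2 and 7 adjusted over the list alone) of 19 (camera adjusted p = 0.0295, and adjusted p = 0.398 with an estimated correlation). Of 16 growth factor and MAPK feedback genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0419, and adjusted p = 0.342 with an estimated correlation). The phosphatase gene Dusp4 rose by 1.63. Of 20 unfolded protein response genes, 2 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0153, and adjusted p = 0.459 with an estimated correlation), and of 9 neutrophil markers, 3 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0256, and adjusted p = 0.393 with an estimated correlation). Lipocalin 2 (Lcn2) rose by 2.43. These calls ended when 1 library was left out (camera adjusted p in parentheses): without sgNC_batch2 replicate 1, cAMP targets (0.185), MAPK feedback (0.0538), unfolded protein response (0.0538) and neutrophil markers (0.0626); without sgNC_batch2 replicate 3, alternative activation (0.0618); without sgPpp2r3c replicate 1, cAMP targets (0.0928) and MAPK feedback (0.0597); without sgHif1a replicate 1, MAPK feedback (0.112). Oxidative phosphorylation genes, not called before (camera adjusted p = 0.0627), were called lower without sgHif1a replicate 1 (camera adjusted p = 0.000652).

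PTGER4 is EP4, a receptor for prostaglandin E2 that raises cAMP. The libraries labelled sgPtger4 were compared with sgNC_batch2 to ask which transcripts changed with that label. Of 13587 genes tested with edgeR, 635 rose and 439 fell, and 2884 had an unadjusted p under 0.05. Cd5l, a secreted macrophage protein, had the largest rise, from 2.88 ± 0.596 to 36.3 ± 4.82 CPM (log2 fold change 3.66, SE 0.37, edgeR adjusted p = 6.13e-05). Lpl, which encodes lipoprotein lipase, rose from 58.9 ± 8.74 to 603 ± 74.5 CPM (log2 fold change 3.36, SE 0.17, edgeR adjusted p = 5.39e-08). Fgl2, a fibrinogen-like protein, rose by 2.67 (SE 0.099, edgeR adjusted p = 3.39e-09) and Tmtc4, a mannosyltransferase gene, by 2.48 (SE 0.27, edgeR adjusted p = 5.03e-05). Arg1 had the largest fall, from 1798 ± 187 to 204 ± 19.5 CPM (log2 fold change -3.14, SE 0.19, edgeR adjusted p = 3.36e-07). Egln3 fell from 123 ± 16.5 to 16.8 ± 2.27 CPM (log2 fold change -2.88, SE 0.14, edgeR adjusted p = 3.11e-08) and Il1b from 251 ± 48.7 to 41.3 ± 2.503 CPM (log2 fold change -2.60, SE 0.23, edgeR adjusted p = 3.50e-05). The chemokine genes Ppbp (log2 fold change -2.39, SE 0.27, edgeR adjusted p = 0.000271) and Cxcl5 (log2 fold change -2.25, SE 0.24, edgeR adjusted p = 5.20e-05) fell. Nos2 fell (log2 fold change -1.72, SE 0.22, edgeR adjusted p = 0.000176) and Vegfa (log2 fold change -1.38, SE 0.12, edgeR adjusted p = 6.33e-06), and Spp1 rose by 0.86 (SE 0.17, edgeR adjusted p = 0.00727). Mrc1, Gpnmb and Cd274 were not called, at 0.17, -0.14 and -0.19, and H2-Ab1 was at -0.73 (SE 0.23, edgeR adjusted p = 0.0685) and was called lower without sgPtger4 replicate 2 (edgeR adjusted p = 0.033). The 1074 calls were 621 without sgPtger4 replicate 1, 641 without replicate 3 and 2487 without sgHif1a replicate 1.

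Glycolysis fell in the libraries labelled sgPtger4, where 1 rose and 15 fell (1 and 17 adjusted over the list alone) of 18 genes, with a median of -0.79 (camera adjusted p = 2.33e-17, and adjusted p = 0.0339 with an estimated correlation). The lactate exporter gene Slc16a3 fell from 489 ± 11.6 to 157 ± 16.7 CPM (log2 fold change -1.64, SE 0.091, edgeR adjusted p = 1.24e-07), and the glucose transporter gene Slc2a1 (log2 fold change -1.15, SE 0.083, edgeR adjusted p = 1.66e-06). Of 24 other HIF-1 targets, 1 rose and 16 fell (1 and 19 adjusted over the list alone, camera adjusted p = 6.09e-16, and adjusted p = 0.0112 with an estimated correlation). The adenylate kinase gene Ak4 fell (log2 fold change -1.80). Of 30 tumour-associated macrophage genes, 1 rose and 13 fell (2 and 16 adjusted over the list alone, camera adjusted p = 2.00e-10, and adjusted p = 0.00326 with an estimated correlation). Thbs1, the matrix protein thrombospondin 1, fell from 4385 ± 705 to 1068 ± 41.5 CPM. Of 19 cAMP and CREB targets, 0 rose and 8 fell (1 and 10 adjusted over the list alone, camera adjusted p = 1.90e-07, and adjusted p = 0.0545 with an estimated correlation). Pde3b fell (log2 fold change -1.73) and Fos fell (log2 fold change -1.21). Of 36 interferon response genes, 16 rose and 0 fell (26 and 0 adjusted over the list alone, camera adjusted p = 3.44e-13, and adjusted p = 0.0689 with an estimated correlation). Ifit2 rose by 1.49. Of 21 p53 targets, 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.041 with an estimated correlation). The stress gene Sesn1 rose by 0.70. Of 16 TGF-beta targets, 0 rose and 4 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.00643, and adjusted p = 0.227 with an estimated correlation). The inhibitor gene Smad6 fell (log2 fold change -1.22). Of 27 ATF4 targets, 9 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00643, and adjusted p = 0.323 with an estimated correlation). The serine synthesis gene Phgdh rose by 2.18. Of 20 unfolded protein response genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00312, and adjusted p = 0.398 with an estimated correlation). Herpud1 rose by 0.55. Of 23 cholesterol biosynthesis genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.000789, and adjusted p = 0.34 with an estimated correlation), with a median of -0.26 that turned to 0.095 on the TPM scale, or -0.13 relative to all genes, whose median that scale moved by 0.22.

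The remaining lists called in the libraries labelled sgPtger4 depended on single libraries. Of 20 NRF2 targets, 6 rose and 2 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.0437, and adjusted p = 0.415 with an estimated correlation). The glutathione synthesis gene Gclm rose by 0.66. Of 5 osteoclast markers Mmp9 and Ctsk fell, also adjusted over the list alone, and the list was called lower (camera adjusted p = 0.0437, and adjusted p = 0.261 with an estimated correlation) with a mean of -0.59 but a median of 0.015, and -0.30 on the TPM scale, or -0.52 relative to all genes. Camera called 3 further lists lower in which edgeR called 0 genes, over all genes and over the list alone. They were nuclear oxidative phosphorylation genes (median -0.36; camera adjusted p = 0.00689, and adjusted p = 0.821 with an estimated correlation), ribosomal protein genes (median -0.31; camera adjusted p = 0.00391, and adjusted p = 0.821 with an estimated correlation) and mitochondrially encoded genes (median -0.36; camera adjusted p = 0.0184, and adjusted p = 0.653 with an estimated correlation). These calls ended when 1 library was left out (camera adjusted p in parentheses): without sgNC_batch2 replicate 1, NRF2 response (0.18), osteoclast markers (0.0711) and mitochondrially encoded genes (0.0601); without sgNC_batch2 replicate 3, oxidative phosphorylation (0.0535), ribosomal proteins (0.0514), osteoclast markers (0.0514) and mitochondrially encoded genes (0.0535); without sgPtger4 replicate 1, oxidative phosphorylation (0.107) and ribosomal proteins (0.0752); without sgPtger4 replicate 2, osteoclast markers (0.111) and mitochondrially encoded genes (0.149); without sgPtger4 replicate 3, NRF2 response (0.0623); without sgHif1a replicate 1, osteoclast markers (0.139). Without sgHif1a replicate 1, 23 of 59 oxidative phosphorylation and 22 of 75 ribosomal protein genes were called lower.

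HIF1A is the oxygen-regulated subunit of the transcription factor HIF-1, which drives glycolysis. The comparison of sgHif1a with sgNC_batch2 asked which transcripts in tumour-exposed macrophages needed it. Of 13587 genes tested with edgeR, 214 rose and 443 fell, and 2153 had an unadjusted p under 0.05. Egln3 had the largest fall, from 123 ± 16.5 to 14.2 ± 0.766 CPM (log2 fold change -3.12, SE 0.14, edgeR adjusted p = 2.73e-08), followed by Ak4, from 57.9 ± 9.73 to 7.22 ± 0.906 CPM (log2 fold change -3.0001, SE 0.15, edgeR adjusted p = 5.03e-08). Nos2 fell from 26.2 ± 2.47 to 3.41 ± 1.124 CPM (log2 fold change -2.93, SE 0.24, edgeR adjusted p = 4.18e-06), the G-protein regulator gene Rgs11 (log2 fold change -2.52, SE 0.17, edgeR adjusted p = 9.33e-07) and Ppbp (log2 fold change -2.40, SE 0.27, edgeR adjusted p = 0.000455). Arg1 fell from 1798 ± 187 to 351 ± 111 CPM (log2 fold change -2.36, SE 0.18, edgeR adjusted p = 3.68e-06) and Vegfa (log2 fold change -0.95, SE 0.12, edgeR adjusted p = 0.000257). Rises were smaller, with the cytokine receptor gene Lifr at 1.41 (SE 0.19, edgeR adjusted p = 0.000557), the sorting receptor gene Sorl1 at 1.41 (SE 0.22, edgeR adjusted p = 0.00194), the endothelin receptor gene Ednrb at 1.26 (SE 0.17, edgeR adjusted p = 0.000508) and the prostaglandin dehydrogenase gene Hpgd at 1.21 (SE 0.24, edgeR adjusted p = 0.00717). Ltc4s, a leukotriene synthase gene, rose by 1.24 (SE 0.30, edgeR adjusted p = 0.0296), by 0.82 without sgHif1a replicate 1, and was not called without sgNC_batch2 replicate 1 (edgeR adjusted p = 0.112) or 3 (0.0907). Cd274 fell (log2 fold change -0.69, SE 0.13, edgeR adjusted p = 0.00617). Il1b fell (log2 fold change -0.85, SE 0.22, edgeR adjusted p = 0.0485), a call that edgeR kept only without sgHif1a replicate 1, with adjusted p of 0.14, 0.089 and 0.0631 without sgNC_batch2 replicate 1, 2 and 3, and 0.174 and 0.14 without sgHif1a replicate 2 and 3. Spp1 and Gpnmb were not called, at 0.035 and -0.10. Mrc1 and H2-Ab1, at 0.38 (SE 0.11, edgeR adjusted p = 0.0555) and -0.62 (SE 0.23, edgeR adjusted p = 0.174), were called higher and lower without sgHif1a replicate 1 (edgeR adjusted p = 0.00355 and 0.0315).

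Of 18 glycolysis genes, 0 rose and 17 fell (0 and 17 adjusted over the list alone) under sgHif1a, with a median of -1.21 (camera adjusted p = 1.94e-34, and adjusted p = 0.00541 with an estimated correlation). Slc16a3 fell from 489 ± 11.6 to 129.7 ± 5.28 CPM (log2 fold change -1.91, SE 0.092, edgeR adjusted p = 2.73e-08) and Eno1, the enolase gene, from 1974 ± 138 to 780.5 ± 80.3 CPM (log2 fold change -1.34, SE 0.095, edgeR adjusted p = 1.16e-06). Of 24 other HIF-1 targets, 0 rose and 16 fell (1 and 18 adjusted over the list alone, camera adjusted p = 7.78e-27, and adjusted p = 0.00326 with an estimated correlation). The kinase gene Pdk1 fell (log2 fold change -1.79). Of 35 cell cycle genes, 0 rose and 31 fell (0 and 35 adjusted over the list alone), with a median of -0.98 (camera adjusted p = 3.47e-39, and adjusted p = 0.0404 with an estimated correlation). The topoisomerase gene Top2a fell from 116 ± 17.6 to 43.1 ± 3.67 CPM (log2 fold change -1.42, SE 0.12, edgeR adjusted p = 4.18e-06). Of 30 tumour-associated macrophage genes, 0 rose and 12 fell (1 and 13 adjusted over the list alone, camera adjusted p = 2.00e-10, and adjusted p = 0.00326 with an estimated correlation). The transglutaminase gene F13a1 fell (log2 fold change -1.89) and Mmp9 fell (log2 fold change -1.95). Of 28 NF-kB targets, 0 rose and 7 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.000951, and adjusted p = 0.0404 with an estimated correlation), with Cxcl3 at -2.04, and their median of -0.061 turned to 0.13 on the TPM scale, or 0.028 relative to all genes.

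Single libraries decided the other results under sgHif1a. The 657 changed genes became 2706 without sgHif1a replicate 1 (1095 higher and 1611 lower, all 657 included) and 432 without replicate 2. Ribosomal protein genes took 5.38% of counts in sgHif1a replicate 1, 2.03% and 2.15% in replicates 2 and 3 and 3.10% to 3.52% in controls. Camera called this list lower (camera adjusted p = 0.0411, and adjusted p = 0.875 with an estimated correlation) while edgeR called 0 of 75, over all genes and over the list alone, and its median of 0.056 and mean of 0.077 were positive, while the median was -0.16 on the TPM scale, or -0.26 relative to all genes. Without sgHif1a replicate 1, 62 of 75 fell (camera adjusted p = 4.40e-27, median -0.70), and the list was not called without sgNC_batch2 replicate 3 (camera adjusted p = 0.292), sgHif1a replicate 2 (0.490) or sgHif1a replicate 3 (0.695), the last 2 with the direction reversed. Oxidative phosphorylation genes went from uncalled (camera adjusted p = 0.594) to 35 of 59 lower (camera adjusted p = 1.33e-12) without that library. Of 36 interferon response genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.000175, and adjusted p = 0.346 with an estimated correlation), with Ifi44 at 1.01, and of 20 unfolded protein response genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.034, and adjusted p = 0.49 with an estimated correlation). Herpud1 rose by 0.44. The unfolded protein response call ended without sgNC_batch2 replicate 1 (camera adjusted p = 0.127), sgNC_batch2 replicate 3 (0.0645) or sgHif1a replicate 1 (0.677). The interferon response call ended without sgHif1a replicate 1 (0.0781).

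Lists not called in any comparison included components of Ragulator, Rag GTPases and mTORC1, with medians of 0.14 under sgLamtor1 and 0.16 under sgFlcn (camera adjusted p = 0.247 and 0.0509), and PP2A subunits, with 0.052 under sgPpp2r3c (camera adjusted p = 0.165). Some lists of cell type markers had too few genes to test. No mast cell marker passed the count filter in any comparison, and of epithelial and 4T1 markers 1 or 2 passed, the most abundant being Lcn2 at 13.6 to 16.6 CPM in the controls, a gene that macrophages also express. The most abundant erythroid or megakaryocyte marker was Pf4 at 1808 to 3463 CPM in the controls, and in batches 1 and 2 the most abundant dendritic cell marker was Irf8 at 296 to 337 CPM. Of 4 dendritic cell markers 2 rose and 2 fell under sgFlcn, and 2 of 2 erythroid or megakaryocyte markers fell under sgLamtor1 and under sgFlcn.

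All 15 pairs of targets were compared by the correlation of log2 fold changes across genes. Guides from different batches share no controls, and among these sgLamtor1 and sgFlcn stood highest, at 0.61. The next were sgRreb1 with sgPpp2r3c at 0.33, sgLamtor1 with sgRreb1 at 0.29 and sgLamtor1 with sgPpp2r3c at 0.25, while sgHif1a had -0.14 with sgLamtor1 and -0.15 with sgRreb1. Within batch 2, sgPpp2r3c and the libraries labelled sgPtger4 had an r of 0.62, where simulated unchanged groups against the same controls gave 0.51, and a covariance of 0.248 against 0.0701. They shared 248 rises and 122 falls, where independent lists would share 27.2 and 9.66. The libraries labelled sgPtger4 and sgHif1a had an r of 0.55 (simulated 0.51), a covariance of 0.195 (simulated 0.0713) and 134 shared falls against 14.3 for independent lists. For sgPpp2r3c and sgHif1a r was 0.34 (simulated 0.49) and the covariance 0.120 (simulated 0.0690). For sgFlcn and sgRreb1 in batch 1, r was 0.19 (simulated 0.48) and the covariance 0.111 (simulated 0.0365). Groups of 3 controls cannot be split into parts of 2, so part of the excess in same-batch pairs may come from the shared controls.

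The 3 control groups were compared to measure how far batches differed without a targeting guide. Of 13253 genes 7272 (54.9%) differed between them (edgeR), and 8027 had an unadjusted p under 0.05. Arg1 stood at 88.6 ± 19.0 CPM in sgNC_batch0, 910.2 ± 65.9 in sgNC_batch1 and 1859.9 ± 199 in sgNC_batch2 (edgeR adjusted p = 7.45e-11). Vegfa stood at 87.2, 186 and 419 CPM (edgeR adjusted p = 3.39e-09), and Hif1a at 541, 404 and 864 CPM (edgeR adjusted p = 1.09e-06). Nos2 and Ppp2r3c were not called (edgeR adjusted p = 0.103 and 0.328). Xist, transcribed from the inactive X chromosome, was at 1144 to 1466 CPM over the libraries of batch 0, at most 0.121 CPM in batch 1 and 232 to 763 CPM in batch 2. The Y-linked gene Ddx3y had 0 counts in batch 0, 57.1 to 98.2 CPM in batch 1 and 15.2 to 21.3 CPM in batch 2. Levels also differed within batches. Xist was lower under sgLamtor1 than in its control (log2 fold change -0.18, edgeR adjusted p = 0.0137), and Ddx3y was lower under sgFlcn (-0.38, adjusted p = 0.00223) and sgRreb1 (-0.33, adjusted p = 0.00617). Xist was at 554 to 763 CPM under sgPtger4 and 355 to 510.3 CPM in its control (no overlap, edgeR adjusted p = 0.191). Of 4 Y-linked genes, 2 were called lower under sgFlcn and 4 under sgRreb1. Each guide was compared with its control within 1 batch. The difference between sgLamtor1 and sgFlcn, the correlations and overlaps between guides of different batches and the comparison of control groups crossed batches.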

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

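Effects of sgLamtor1 and sgFlcn that differed by the test of the difference drew attention here. The genes and 15 lists below came from a rule set in advance, while the taking apart of regroupings by batch, the closeness of groups, the list tests without single libraries and the list medians on other scales were chosen only after the result was seen. Log2 fold changes under sgLamtor1 minus those under sgFlcn compared responses, not levels. They were positive for Mmp9 (4.27), Cd38 (3.13), St3gal5 (ganglioside synthase, 2.68), Hdac9 (histone deacetylase, 2.66) and Gda (guanine deaminase, 2.16). They were negative for Scd2 (-4.71), Stac2 (-3.66), Cd74 (-2.76) and Adgre5 (adhesion receptor, -2.56). None of these lost its call without a library or in the alternatives run for differences (not limma-voom, TPM, 6 libraries or length trends).

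Lists are given as the median difference, camera adjusted p, and adjusted p with an estimated correlation. Positive were cell cycle (0.68, 2.37e-14, 0.147), MAPK feedback (1.05, 4.11e-07, 0.064), interferon response (0.33, 0.000376, 0.266) and tumour-associated macrophage genes (0.45, 0.00855, 0.089). So were p53 targets (0.40, 0.0271, 0.0745), unfolded protein response (0.33, 0.0336, 0.383) and fibroblast markers (1.81, 0.0336, 0.363). Negative were cholesterol biosynthesis (-1.46, 6.20e-27, 9.96e-05), MHC class II (-0.68, 1.98e-05, 0.0194), mitochondrially encoded genes (-0.84, 0.00011, 0.36) and lipid handling (-0.54, 0.00191, 0.0171). So were HIF-1 targets (-0.25, 0.0115, 0.202), cAMP targets (-0.29, 0.0336, 0.253), monocyte markers (-0.69, 0.0336, 0.231) and MHC class I (-0.16, 0.0336, 0.383). The calls of cholesterol biosynthesis, MHC class II and lipid handling held with an estimated correlation. No median changed sign under RLE or on the TPM scale. Leaving out each of 12 libraries kept 11 of 15 calls. Monocyte markers were lost without sgNC_batch0 replicate 1 (camera adjusted p = 0.0564) or sgNC_batch1 replicate 1 (0.0525), and MHC class I without sgNC_batch0 replicate 1 (0.0564), sgLamtor1 replicate 2 (0.0784), sgNC_batch1 replicate 2 (0.101) or sgFlcn replicate 3 (0.0632). Fibroblast markers were lost without sgNC_batch0 replicate 3 (0.107), sgNC_batch1 replicate 1 (0.065) or sgFlcn replicate 2 (0.0772), and the unfolded protein response without sgLamtor1 replicate 2 (0.0502) or sgNC_batch1 replicate 1 (0.0693).

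Of 100 random regroupings of libraries within each batch, the real one included, 8 gave at least the 1875 differing genes of the real groups, and the highest other count was 3215. The other 7 kept the real groups of 1 batch, and with them the whole effect of 1 guide, so they do not measure chance. The 79 that moved libraries in both batches called at most 1 gene, but they mix targets with controls, which widens the spread within groups, so they do not measure it either. Chance was therefore not excluded by regrouping. The target groups lay closer together than the control groups for 1286 of the 1875 genes (68.6%), for 10 of the 10 genes with the firmest difference and for 7060 of 12488 other genes (56.5%). Each target was in 1 batch only, so batch and the sex of its cells were not separable from target. No biological explanation was tested.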

How the results depend on the processing

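Changed-gene counts stayed within 1.5 times the reported count under RLE, no filter, a mean CPM of at least 5, DESeq2 and limma-voom in all 6 comparisons. With an absolute log2 fold change of at least 1 they were 1414 (sgLamtor1), 1190 (sgFlcn), 853 (sgRreb1), 290 (sgPpp2r3c), 343 (sgPtger4) and 268 (sgHif1a), since fewer genes pass. With an adjusted p under 0.01 they were 3121 (sgRreb1), 461 (sgPpp2r3c), 534 (sgPtger4) and 356 (sgHif1a), for the same reason. With log2(TPM + 1) they were 3162 (sgRreb1), 326 (sgPpp2r3c, 279 up and 47 down), 427 (sgPtger4, 333 up and 94 down) and 213 (sgHif1a, 47 up and 166 down). In sgFlcn that scale gave 1452 up and 2667 down, where counts gave 2507 and 2517, and in sgLamtor1 2113 and 2895, where counts gave 3367 and 3265. For sgPpp2r3c, sgPtger4 and sgHif1a in turn, 1 model of 27 libraries gave 1723, 2186 and 1340, a model of the 6 compared libraries 1868, 1637 and 224, and removal of length trends 1519, 1678 and 1164. Without sgHif1a replicate 1, sgPpp2r3c had 1824 and sgPtger4 2487. The cause was not tested for the TPM, 27-library, 6-library, length and left-out counts.

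With an estimated correlation camera called 1 list (sgLamtor1), 3 (sgFlcn), 1 (sgRreb1), 2 (sgPpp2r3c), 4 (sgPtger4) and 5 (sgHif1a), and fry called 26 (sgLamtor1), 19 (sgFlcn) and 23 (sgRreb1), the cause not tested. Similarity at a mean CPM of at least 5 moved to 0.37 for sgLamtor1 and sgPpp2r3c, 0.48 for sgRreb1 and sgPpp2r3c and 0.17 for sgPpp2r3c and sgHif1a. Under sgHif1a the cytosolic ribosomal list reversed without replicate 2 (camera adjusted p = 0.490) and 3 (0.695), and was at 4.40e-27 without replicate 1.

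Leaving out 1 library at a time gave 5617 to 6426 changed genes (sgLamtor1), 4102 to 6183 (sgFlcn), 3660 to 5750 (sgRreb1), 489 to 688 (sgPpp2r3c), 621 to 951 (sgPtger4), 432 to 2706 (sgHif1a), 1151 to 2382 (difference of sgLamtor1 and sgFlcn) and 6059 to 7689 (controls). Called lists ranged over 10 to 11 (sgLamtor1), 7 to 15 (sgFlcn), 9 to 13 (sgRreb1), 10 to 14 (sgPpp2r3c), 11 to 15 (sgPtger4) and 6 to 10 (sgHif1a), and 24 of 71 calls ended without some library. Named gene results kept direction and call in 437 of 440 under DESeq2, 437 of 440 under RLE, 428 of 430 under limma-voom, 429 of 429 at a mean CPM of at least 5, 427 of 440 without a filter, 414 of 430 with 27 libraries, 414 of 430 with 6, 424 of 430 without length trends and 377 of 429 on the TPM scale. Named lists kept theirs in 70 of 71 under RLE, 64 of 70 at a mean CPM of at least 5 and 64 of 71 under fry. Sign changes between values that both missed the threshold were not counted as changes (30 over 14 genes between settings, lowest adjusted p 0.688, and 21 over 11 genes between left-out libraries, lowest 0.113). In batch 0 the replicate numbers did not pair (r between control and target of the same number -0.0134, 0.0532 and -0.000361), and a block on them gave 6714 changed genes, 11 lists and 1681 differing genes. In batches 1 and 2, column names of each group end in 1, 2 or neither. Libraries with the same ending did not pair (r with the control -0.106 to 0.152). A replicate block by column ending, chosen after seeing the data, gave 5118 changed genes (sgFlcn), 4880 (sgRreb1), 746 (sgPpp2r3c), 907 (sgPtger4) and 561 (sgHif1a), 1626 differing genes and 6843 for the controls. It kept 354 of 364 named gene results and 56 of 60 list calls. At 14042494 to 22385715 counts per library and n = 3, changes of 1.5-fold were found less often than larger ones in simulations for every comparison.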

Other observations

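Calls shared by all 6 comparisons were counted only after the values had been seen, and the tests of sgHif1a replicate 1 and the test of a shared shift of Ptger4 below were also chosen only after the result was seen. Of 12503 genes tested in every comparison, 1 rose in all 6 and 8 fell in all 6. The gene that rose was Axl, a receptor kinase that takes part in clearing dying cells. The genes that fell were Arg1, Hif1a, the hypoxia genes Bnip3, Egln1 and Pfkl, the arrestin-domain gene Arrdc3, the selenium-binding protein gene Selenbp1 and the kinase gene Stk24. Independent lists would share 0.00411 and 0.00322 genes, though comparisons in the same batch share controls and are not independent.

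Genes that fell with sgHif1a did not fall together with every other guide. Of 442 such genes, Hif1a left out, 438 had a value under sgLamtor1, where 246 rose and 76 fell, with a median log2 fold change of 0.34 (95% of random lists gave -0.039 to 0.051). The HIF-1 target list itself did fall there (14 of 23, median -0.61), while of 35 cell cycle genes 31 fell under sgHif1a and 31 rose under sgLamtor1. Neither list call under sgLamtor1 held with an estimated correlation (adjusted p = 0.346 and 0.491). Under sgRreb1, 173 rose and 51 fell, with a median of 0.18 (random -0.034 to 0.040). Under sgFlcn, 79 rose and 134 fell, with a median of -0.12 (random -0.050 to 0.022). The median fell only under sgFlcn, although Hif1a mRNA was lower under each of the 3. Random lists ignore that genes move together and cannot decide if the fall is shared. Guides of batch 2 share controls with sgHif1a and were not tested.

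The library sgHif1a replicate 1 lay apart from the other 2 of its group. Length bias could account for part of this. The mean SD of its log2 differences from the other 2 was 0.641, and 0.418 after a length trend was removed. That stayed above the 0.353 of the next pair in the batch. Unedited cells were unlikely. Over 34 glycolysis and HIF-1 target genes its median position was 0.931 (quartiles 0.726, 1.06), with 0 at controls and 1 at the other 2. A wrong label was not excluded, as both lists also fell in sgPtger4. No biological explanation was tested.

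Ptger4 mRNA rose in the libraries labelled sgPtger4. A shift shared by the guides of batch 2 was not seen, since Ptger4 lay at -0.39 (SE 0.125) under sgPpp2r3c and 0.12 under sgHif1a. Length bias was not likely the cause, since the log2 fold change was 0.72 (SE 0.11, edgeR adjusted p = 0.000137) after length trends were removed. Whether the guide edited the locus could not be read from these counts, and no biological explanation was tested.

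With 3 libraries against 3 there are 10 regroupings, so the share with as many called genes cannot fall under 0.05 (smallest 0.1). The real and the highest other counts were 6632 and 0 (sgLamtor1), 5024 and 0 (sgFlcn), 4811 and 0 (sgRreb1), 882 and 0 (sgPpp2r3c), 1074 and 1 (sgPtger4) and 657 and 932 (sgHif1a), so that 1 of 10 had as many in the first 5 comparisons and 2 of 10 in the last. The regrouping with 932 put sgNC_batch2 replicate 1 with sgHif1a replicates 2 and 3. For the 3 control groups, 1 of 100 random regroupings, the real one, had as many as 7272, and the highest other count was 1982.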
